A study of Homo sapiens with 8 samples.

How the data were processed

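RNA-seq of 8 libraries of BE(2)-M17 neuroblastoma cells was used, 4 untreated and 4 after IFN-γ, grouped by the treatment given in the labels, with the replicate number from the sample titles. Per the labels' protocols, RNA was isolated with TRIzol, ribosomal RNA was depleted, and libraries were made with a kit that does not mark strand and sequenced as pairs on a HiSeq. The growth protocol also names the SH-SY5Y line, and all 8 samples are labelled M17. The deposited values are FPKM per gene, 1 column per library. Per the submitters' processing notes, reads were aligned with TopHat2 to hg38 and values were made with Cuffdiff, with no versions or options given. The annotation used, and whether Cuffdiff scaled libraries to each other, are not given in the sources used here. FPKM divides by transcript length and by fragments mapped, so it is a relative measure, and a very abundant RNA can lower all other values if it is counted in that total. No counts were given, so count models were not used.

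The table held 26372 gene symbols, each once, of which 6347 were at 0 in all 8 libraries. The 13598 genes with a mean of at least 0.5 FPKM were tested. Values were used as log2(FPKM + 0.1), without further scaling. Groups were compared by limma with a mean-variance trend (limma 3.58.1, R 4.3.3), two-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. For MIAT an exact two-sided permutation test was added. 35 gene lists holding 708 different symbols, 21 of them in more than 1 list, covered the interferon response, signalling, neuronal identity, schizophrenia candidate genes, stress, metabolism, reference genes and markers of other cells. The 33 lists with at least 3 tested members were tested by limma's camera, which compares a list with all other genes, at a preset correlation of 0.01, with adjustment over the lists. A list held if it passed with the same direction with the correlation estimated from the residuals. Fry, a rotation test of whether a list's genes move on balance in 1 direction, was an alternative.

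Genes named were MIAT, the 15 largest rises and 10 largest falls among called genes with a mean of at least 1 FPKM in the higher group and no overlap between groups, up to 4 called members per list with the largest change, up to 2 of the highest members of a list with fewer than 2 called, and a fixed set (among them IRF1, SOCS1, IFNGR1, IFNGR2, JAK1, JAK2, DISC1, ERBB4, C4A, MYCN, ACTB and GAPDH). H3F3A and the genes named only in the closing section were chosen after their values were seen. Some genes that the rule names are not reported here. The lists, the tests, this rule and the alternatives (pseudocounts of 1 and 0.01, no filter, a filter at 1 FPKM, median-of-ratios scaling, quantile normalization, rescaling to TPM, short RNA genes left out, limma without the trend or with robust fitting, the replicate number as a block, each library left out and, for lists, the estimated correlation and fry) were fixed before the data were examined. Rescaling to TPM without the short RNA genes, and removal of a trend with transcript length by lowess with a span of 0.3, were added afterwards.

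Depth was estimated from the steps of low FPKM values, which are whole multiples of what 1 fragment is worth for a gene of given length. Relative to untreated replicate 1 the depth ran from 0.859 in IFN-γ replicate 2 to 1.252 in IFN-γ replicate 4. 1 fragment per kilobase was worth 0.0482 to 0.0703 FPKM, which sets the precision of low values. These depths are approximate and cover fragments on the scale of the FPKM denominator. Replicates were compared before averaging over 307 to 310 genes. In the 9 pairs of a group without IFN-γ replicate 4 the variance was 1.56 to 2.00 times the counting variance, and in the 3 pairs with it 7.56 to 8.51 times, so no pair differed by less than sampling noise and each library was counted.

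Positions, lengths and gene types came from GENCODE release 29 on GRCh38, the assembly that hg38 names, in which 89.95% of the symbols matched a single gene. Genes with near-identical copies (HLA genes, C4A, IFITM1, GBP1 and GBP1P1, histone, protocadherin and metallothionein genes) and genes that overlap others or lie antisense to them are uncertain, because fragments can be divided between them in ways the values do not show. An FPKM of exactly 0 is given as listed at 0, with each library's value, or, where part of a group is at 0, by the highest value of that group, and no fold is given.

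The fit was tested on simulated data for the comparison of IFN-γ with untreated cells, with 13598 genes of which 200 were changed. At the threshold it recovered 42% of 1.25-fold, 64% of 1.5-fold, 86% of 2-fold and 98% of 4-fold changes, 50 simulated at each size, and 8 of 153 calls (5.23%) were false. None of the 33 lists was called without a simulated change, and a shifted list of 20 genes was called at adjusted p = 1.1e-48. Only 200 genes were changed in the simulation, while 3039 were called in the real data. The adjustment was therefore stricter in the simulation, and the recovered shares need not hold for the real comparison. The simulated genes were drawn independently of each other, so the list test was not tried on correlated genes. In the real data the estimated correlation reached 0.953, in the ribosomal protein list. Summaries and figures were made with Python 3.11.15.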

Results

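RNA was measured in BE(2)-M17 cells, an established human neuroblastoma line of catecholaminergic type. 4 libraries came from untreated cells and 4 from cells given interferon-γ (IFN-γ, a cytokine made by T cells and natural killer cells) at 10 ng/ml for 24 h. Each library was made from 1 µg of total RNA depleted of ribosomal RNA, with paired reads of 150 nt and a target of 100 M reads, in which M is mega. The values are FPKM per gene, the fragments per kilobase of transcript scaled to a total of mapped fragments. Which fragments entered that total is not given. The steps between low FPKM values placed the depth at about 14.2 to 20.7 M fragments per library on the scale of the deposited values. The labels do not say that the 4 libraries of a group came from separate cultures, so each p-value measures the spread between these libraries, which may be technical. The comparison asks which RNAs changed with IFN-γ, and the series title singles out the long non-coding RNA GOMAFU (gene symbol MIAT), interferon response genes and schizophrenia. Below, values are FPKM means ± SD over the 4 libraries of a group (n = 4), untreated first, and changes are on the log2(FPKM + 0.1) scale, which understates the change of low genes.

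Genes of the interferon response rose with IFN-γ, several of them from near 0. GBP1, a guanylate-binding GTPase of cell-autonomous immunity, rose from 0.0240 ± 0.0106 to 546 ± 15.5 FPKM, and TAP1, the peptide transporter of antigen presentation, from 0.131 ± 0.0636 to 353 ± 18.5. WARS, the tryptophanyl-tRNA synthetase, rose from 24.3 ± 0.490 to 722 ± 14.8 FPKM. MIAT fell from 8.41 ± 0.411 to 4.73 ± 0.330 FPKM, and DCX, a microtubule-associated protein of immature neurons, from 19.6 ± 0.722 to 7.62 ± 0.517.

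Of 13598 genes tested, 3039 passed a limma adjusted p of 0.05, 1809 higher and 1230 lower with IFN-γ. Rises were larger than falls: 386 genes were at least 2-fold higher and 37 at least 2-fold lower, and 70.1% of the called genes changed by less than 1.5-fold. In 3838 genes, 28.2% of those tested, the 4 values of a group lay entirely above the 4 of the other, where chance gives 2.86%. Of 33 gene lists tested, camera called 18 higher and 2 lower, and with an estimated correlation 11 higher and 0 lower. Fry, which asks whether a list's genes move on balance in 1 direction, called 26 higher and 1 lower. The first principal component separated the groups and held 73.0% of the variance. Pearson's r of log2 values was at least 0.983 between libraries of a group and at most 0.938 between groups. The balance of higher and lower calls depended on the scaling: quantile normalization gave 1470 higher and 2564 lower. Rescaling to TPM moved the median of all genes by 0.79 (log2) and gave 9536 higher and 19 lower, where SNORD3A alone held 5.97 to 57.9% of the FPKM sum of the untreated libraries and none of it with IFN-γ. In the deposited values the median FPKM of tested genes was 8.97, 8.96, 8.93 and 8.98 in the untreated libraries. SNORD3A held 53.2, 57.9, 5.97 and 55.7% of their FPKM sums. With IFN-γ, where it was at 0, the medians were 9.25, 9.26, 9.28 and 9.14. These medians argue against SNORD3A having lowered the other deposited values, so the shift arises in the rescaling itself. Of the called falls of single genes named here, those of SNORD3A, DGKK, NPPC, LPPR4, KIAA0125 and SOCS2 passed in TPM. The others, MIAT and DCX among them, did not pass there in either direction, which the shift of all genes alone can bring about. Without the short RNA genes, TPM gave 1201 higher and 1752 lower. IFN-γ replicate 4 stood apart from the other 3 IFN-γ libraries, and without it 2157 genes were higher and 1698 lower.

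**Figure D1:**
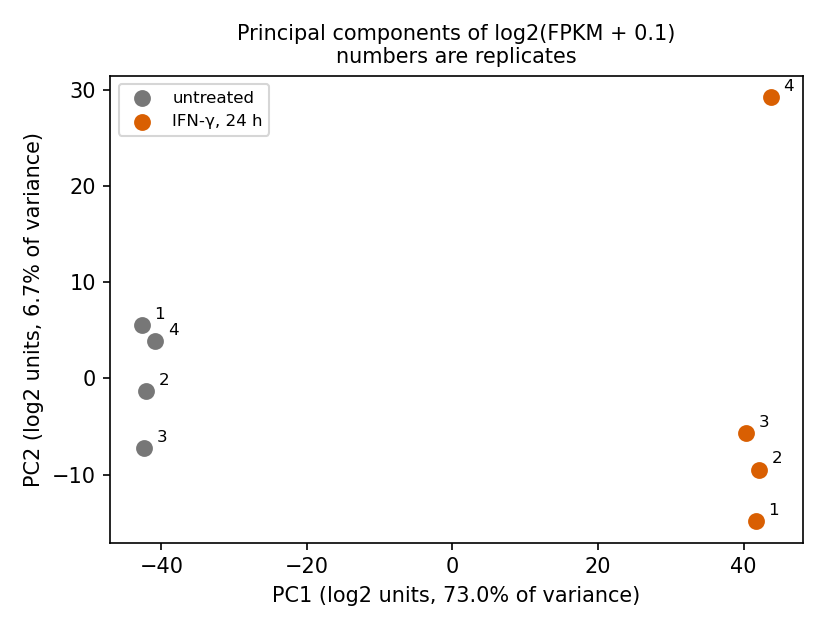
Principal component analysis of log2(FPKM + 0.1) over the 13598 tested genes. Each point is a library, with the first component (73.0% of the variance) on the horizontal axis and the second (6.72%) on the vertical axis, both in log2 units. The groups separate on the first component, and IFN-γ replicate 4 lies at 29.3 on the second, above the other 7 libraries.

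MIAT lies on chromosome 22, from 26646428 to 26676475 on the forward strand of GRCh38 in GENCODE release 29, which annotates it as a long intergenic non-coding RNA. Its FPKM was 8.18, 8.57, 7.98 and 8.90 in the untreated libraries and 4.91, 4.99, 4.78 and 4.26 with IFN-γ, lower in each of the 4. The log2 change was -0.82 (SE 0.07, limma adjusted p = 1.1e-05), and the exact two-sided permutation test gave p = 0.0286, the smallest that its 70 arrangements allow. Rescaled to TPM, the MIAT change was -0.024 (adjusted p = 0.943, against 3.1e-06 to that value over all alternatives), which is -0.81 relative to the shifted median. By the longest annotated transcript and the depth these FPKM stand for about 720.1 to 1699 fragments per library.

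**Figure D2:**
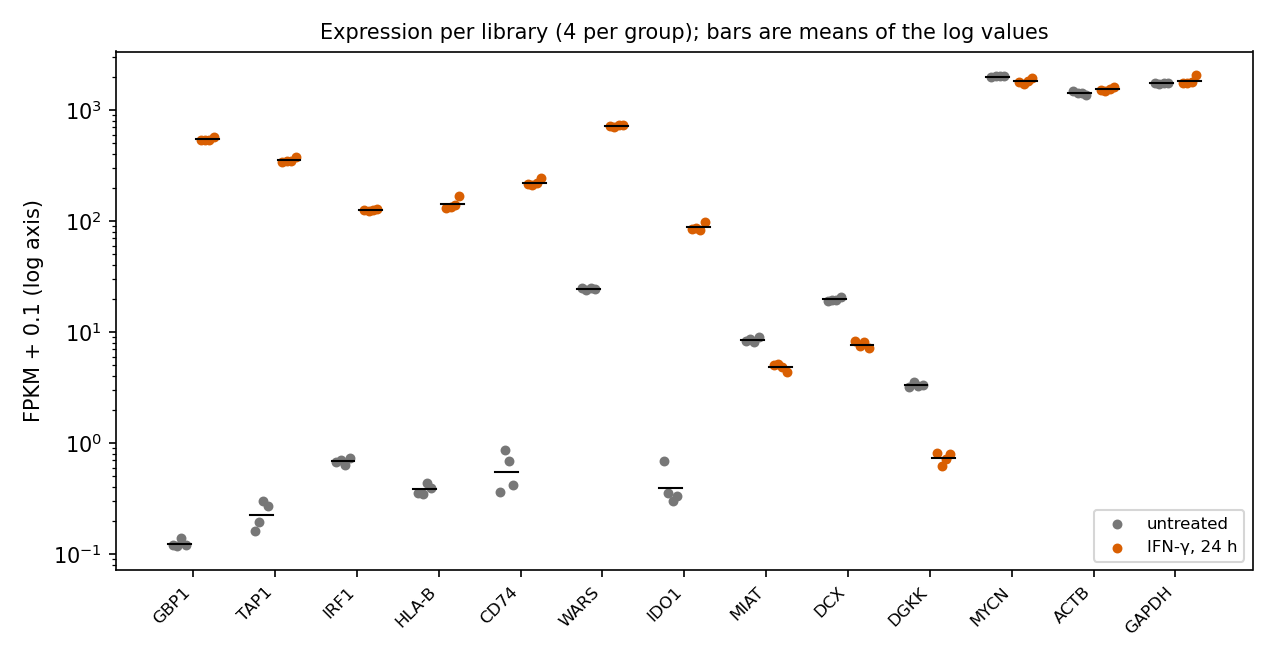
FPKM of 13 genes in each library, on a log axis after adding 0.1 FPKM. Grey points are untreated and orange points IFN-γ libraries, and short bars are group means of the plotted log values. MIAT, DCX and DGKK lie lower with IFN-γ in each library, and 7 genes lie higher in each library. ACTB, GAPDH and MYCN did not pass the test, although ACTB lies higher and MYCN lower with IFN-γ in each library.

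The components of IFN-γ signalling responded unequally. Of 12 tested genes of the receptor and the JAK-STAT pathway, 8 rose and none fell (camera adjusted p = 6.2e-10, held with an estimated correlation). IRF1, a transcription factor of the interferon response, rose from 0.584 ± 0.0404 to 125 ± 2.14 FPKM (log2 change 7.52, SE 0.05) and JAK2, a receptor-bound kinase, from 1.75 ± 0.203 to 19.8 ± 0.520. JAK1 rose from 19.5 ± 0.871 to 21.7 ± 0.160, a call lost without untreated replicate 1 or 2 or IFN-γ replicate 1 or 2 (adjusted p = 0.0515 to 0.0730) and over all alternatives at 0.0136 to 0.484. The receptor chains did not pass the test: IFNGR1 was at 19.2 ± 0.910 and 20.8 ± 1.73 FPKM and IFNGR2 at 18.3 ± 1.37 and 18.6 ± 0.966. All 7 tested interferon regulatory factors and their partners passed, 6 higher and 1 lower, among them IRF9 (4.64 ± 0.605 to 43.9 ± 2.66 FPKM), BATF2 (at most 0.0975 in an untreated library, 12.3 ± 0.339 with IFN-γ) and IRF7 (0.623 ± 0.155 to 2.00 ± 0.309). This list was called higher by camera (adjusted p = 1.0e-07), with adjusted p = 0.0596 with an estimated correlation. Of 16 negative regulators of cytokine signalling, 4 rose and 1 fell. SOCS1, a feedback inhibitor of JAK kinases, rose from 0.0845 ± 0.0592 to 18.1 ± 1.72 FPKM, USP18 from 0.290 ± 0.146 to 8.57 ± 1.06 and SOCS3 from 1.93 ± 0.224 to 5.93 ± 0.138, while SOCS2 fell from 1.12 ± 0.189 to 0.332 ± 0.169. Camera gave adjusted p = 0.0387 for these regulators (adjusted p = 0.121 with an estimated correlation), and adjusted p = 0.0564, 0.0656 and 0.0570 without IFN-γ replicate 1, 2 or 3 (over all alternatives 4.4e-07 to 0.121). Adjusted over the list alone, 8, 6 and 5 members rose in the 3 lists, and 0, 1 and 1 fell.

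Antigen presentation genes rose in both classes. Of 21 tested genes of MHC class I presentation and the immunoproteasome, 20 rose, and of 17 of class II, 15 rose. Adjusted over the list alone, the counts were 20 and 15. HLA-B rose from 0.284 ± 0.0420 to 142 ± 16.9 FPKM and HLA-E from 1.21 ± 0.0933 to 103 ± 3.60. PSMB9, a catalytic immunoproteasome subunit, was listed at 0 in 4 of 4 untreated libraries and at 39.8, 37.5, 39.5 and 48.8 FPKM with IFN-γ. CD74, the class II invariant chain, rose from 0.481 ± 0.233 to 222 ± 14.3 FPKM and HLA-DPA1 from 0.182 ± 0.0908 to 49.9 ± 3.78. HLA-DRA was at most 0.0456 FPKM in any untreated library and at 161 ± 15.7 with IFN-γ, and HLA-DRB1 was listed at 0 in 4 of 4 untreated libraries and at 15.5, 11.5, 14.4 and 15.4 with IFN-γ. Both lists were called higher by camera (adjusted p = 4.6e-32 and 1.2e-20) and held with an estimated correlation. HLA genes share near-identical sequence, so the division of FPKM among them is uncertain.

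Antiviral genes formed the largest group of rises among the fixed lists. Of 48 tested antiviral interferon-stimulated genes, 47 rose and none fell. IFIT3 rose from 0.316 ± 0.0472 to 105 ± 1.96 FPKM and IFI27 from 1.34 ± 0.568 to 214 ± 36.7. IFI44 was at most 0.113 FPKM untreated and at 50.8 ± 5.91 with IFN-γ, and IFITM1, whose paralogs share sequence, at most 0.102 and at 49.8 ± 7.70. Of 7 guanylate-binding and related GTPases, 6 rose, with GBP2 from 0.402 ± 0.108 to 314 ± 7.67 FPKM, GBP4 from at most 0.0556 to 46.1 ± 2.67, and GBP5 listed at 0 in 4 of 4 untreated libraries and at 23.6, 24.9, 23.4 and 22.4 with IFN-γ. All 5 tested apolipoprotein L genes rose, such as APOL6 from 0.0263 ± 0.0151 to 78.3 ± 5.98 FPKM and APOL4 from 0.0566 ± 0.0305 to 67.2 ± 1.35, with APOL1 at most 0.0183 untreated and 70.2 ± 6.52 with IFN-γ, and APOL3 at most 0.0296 and 24.1 ± 0.694. All 8 TRIM ubiquitin ligases tested rose, with TRIM21 from 0.990 ± 0.192 to 15.0 ± 1.33 FPKM and TRIM56 from 2.33 ± 0.102 to 8.85 ± 1.78. Of 11 nucleic acid sensors and adaptors, 8 rose, among them the RNA helicase DDX58 (RIG-I) from 0.675 ± 0.0958 to 12.5 ± 0.244 FPKM and the DNA sensor AIM2 from 0.187 ± 0.0528 to 1.248 ± 0.178, while IFIH1 (MDA5) and TLR3 were listed at 0 in 4 of 4 untreated libraries and reached 6.85, 6.56, 6.92 and 6.53 and 1.56, 1.29, 1.45 and 1.73. Adjusted over the list alone, the counts were 47, 6, 5, 8 and 8. Camera called all 5 lists higher, at adjusted p from 2.6e-62 to 4.0e-09, and all held with an estimated correlation.

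Secreted and surface immune genes rose as well. Of 10 tested chemokines and cytokines, 9 rose. The T-cell attracting chemokines CXCL9, CXCL10 and CXCL11 were listed at 0 in 4 of 4 untreated libraries and reached 39.2, 38.0, 40.6 and 40.2, 4.85, 5.45, 3.95 and 5.34, and 11.2, 11.2, 9.98 and 11.8 FPKM. IL18BP, a soluble inhibitor of interleukin-18, rose from 4.58 ± 0.277 to 103 ± 3.06. Of 5 checkpoint genes, 4 rose, with CD274 (PD-L1) from 0.234 ± 0.0863 to 16.5 ± 0.537 FPKM and CD47 from 19.9 ± 0.423 to 57.1 ± 0.411, while PVRL2 and PVR rose by 0.45 and 0.22 on the log2 scale. Of 8 genes of tryptophan and kynurenine metabolism, 4 rose. IDO1, which opens the indole ring of tryptophan, rose from 0.319 ± 0.185 to 87.5 ± 6.94 FPKM, CCBL2 from 21.3 ± 0.502 to 49.7 ± 5.10 and AADAT from 15.7 ± 0.850 to 17.8 ± 0.913. AADAT lost its call without untreated replicate 1, 2 or 3 or IFN-γ replicate 1 (adjusted p = 0.0637 to 0.107) and PVR without untreated replicate 4 or IFN-γ replicate 2 (0.0543 and 0.0508), with highest adjusted p over all alternatives of 0.342 and 0.317. Of 10 complement genes, 7 rose and 1 fell, with SERPING1, the C1 inhibitor, rising from 0.706 ± 0.235 to 80.3 ± 5.02 FPKM, C1R from 0.382 ± 0.0756 to 13.1 ± 1.16 and C1S from 0.403 ± 0.0834 to 8.51 ± 0.177. Camera gave adjusted p = 5.5e-14, 6.8e-05, 9.4e-04 and 2.5e-06 for these 4 lists. With an estimated correlation the adjusted p was 0.0939 for the checkpoint genes and 0.123 for the tryptophan genes, and the other two lists held. Adjusted over the list alone, 9, 4, 4 and 7 rose, and 0, 0, 1 and 1 fell.

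Of 26 tested genes of apoptosis and pyroptosis, 17 rose and 2 fell (camera adjusted p = 2.7e-08, held with an estimated correlation). CASP1, the inflammasome caspase, was listed at 0 in 4 of 4 untreated libraries and at 5.97, 5.87, 6.52 and 7.52 FPKM with IFN-γ. CASP10 rose from 0.0539 ± 0.0339 to 2.17 ± 0.316 FPKM, the death receptor FAS from 0.141 ± 0.0789 to 2.35 ± 0.112 and the pore-forming GSDMD from at most 0.0734 to 1.21 ± 0.298. The NF-κB list was not called (camera adjusted p = 0.626): of 13 tested, 3 rose and 1 fell. ICAM1, an adhesion molecule, rose from 0.0710 ± 0.0306 to 7.23 ± 0.521 FPKM and SOD2, mitochondrial superoxide dismutase, from 16.3 ± 1.78 to 25.2 ± 0.6739, NFKBIZ from 1.78 ± 0.176 to 2.36 ± 0.107, and NFKBIE fell from 15.4 ± 0.512 to 12.4 ± 0.392. NFKBIZ lost its call without untreated replicate 2 (adjusted p = 0.0525, over all alternatives 0.00564 to 0.0993). The NF-κB median log2 change was -0.0033 and the mean 0.45. Adjusted over the list alone, 17 and 3 rose and 2 and 1 fell.

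**Figure D3:**
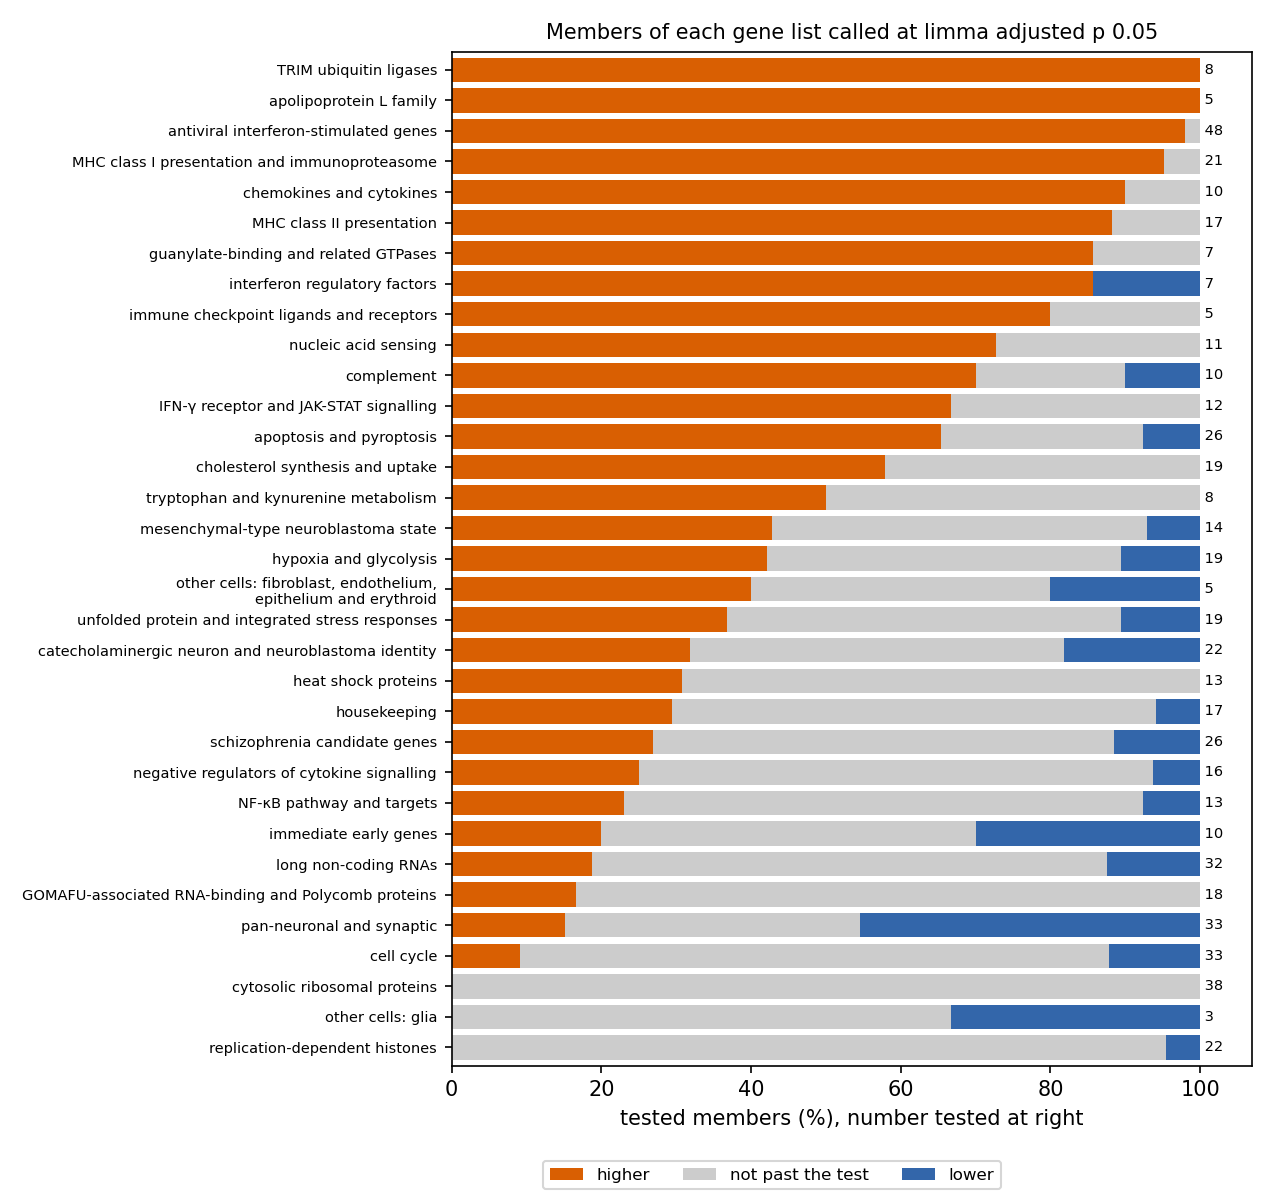
Members of each gene list that were higher (orange), lower (blue) or not past a limma adjusted p of 0.05 (grey), as a percentage of tested members, with the number tested beside each bar. Lists are ordered by the share higher. 47 of 48 antiviral genes were higher, and 15 of 33 pan-neuronal and synaptic genes were lower.

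Neuronal genes changed in both directions, with smaller changes. Of 33 tested pan-neuronal and synaptic genes, 15 fell and 5 rose (16 and 6 adjusted over the list alone). DCX fell by 1.35 on the log2 scale and GAP43, a growth cone protein, fell from 27.9 ± 1.78 to 17.3 ± 0.872 FPKM, while the RNA-binding protein gene ELAVL4 rose from 53.1 ± 1.01 to 89.3 ± 2.29 and MAP1B from 221 ± 1.63 to 351 ± 31.7. Camera called the list lower (adjusted p = 0.00859), with adjusted p = 0.158 with an estimated correlation and 0.446 in TPM. The catecholaminergic and neuroblastoma identity list was not called (adjusted p = 0.626): 7 of 22 rose and 4 fell, the same counts adjusted over the list alone, with a median log2 change of -0.01 and a mean of 0.06. The receptor kinase gene ALK rose from 0.874 ± 0.0750 to 1.52 ± 0.172 FPKM. SLC18A1, a vesicular monoamine transporter, fell from 11 ± 0.647 to 6.06 ± 0.426 and the nuclear receptor gene NR4A2 from 3.75 ± 0.230 to 2.26 ± 0.326. MYCN, which is amplified in this line, did not pass the test at 2003 ± 26.1 and 1817 ± 93.0 FPKM. It was called lower without IFN-γ replicate 4 (log2 change -0.17, adjusted p = 0.00104), with quantile normalization (-0.26, 0.00681) and in TPM without the short RNA genes (-0.23, 4.6e-04), and higher in TPM with them (0.66, 0.041), with adjusted p from 4.6e-04 to 0.423 over all alternatives. The mesenchymal-state list was not called (adjusted p = 0.138), with 6 of 14 higher and 1 lower (7 and 3 adjusted over the list alone). In it SNAI2 rose from 5.90 ± 1.08 to 11.1 ± 1.00 FPKM and COL1A1 fell from 1.86 ± 0.0528 to 1.37 ± 0.17, a call lost without untreated replicate 2, 3 or 4 (adjusted p = 0.0550, 0.0567 and 0.0607, over all alternatives 0.00509 to 0.369).

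The schizophrenia candidate list was not called (camera adjusted p = 0.580): 7 of 26 tested genes rose and 3 fell (7 and 4 adjusted over the list alone). The complement gene C4A rose from 0.0581 ± 0.00937 to 1.69 ± 0.230 FPKM (log2 change 3.50, SE 0.19). This level is uncertain because C4B, a near-identical copy, was listed at 0 in all 8 libraries. Fragments of both genes may be counted as C4A. The dopamine receptor gene DRD2 fell from 7.09 ± 0.570 to 3.81 ± 0.378 and NRG1, a ligand of ERBB receptors, rose from 2.55 ± 0.283 to 4.57 ± 0.438. DISC1 did not pass the test, at 4.02 ± 0.409 and 3.56 ± 0.507 FPKM (adjusted p = 0.311). ERBB4 lay below the FPKM filter and was not tested, at 0.0938 ± 0.0146 and 0.0653 ± 0.0160 FPKM. Among 18 RNA-binding and Polycomb proteins linked to GOMAFU, 3 rose and none fell (adjusted p = 0.291, not called; 3 adjusted over the list alone). Beside ELAVL4 these were the splicing regulator genes CELF3, from 9.06 ± 0.433 to 11.7 ± 1.00 FPKM, and QKI, from 4.28 ± 0.15 to 5.37 ± 0.117. Both missed the threshold in TPM without the short RNA genes (adjusted p = 0.0681 and 0.0757, the highest over the alternatives).

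Of 32 tested long non-coding RNAs on the fixed list, 6 rose and 4 fell (7 and 4 adjusted over the list alone). HCP5, in the MHC region, rose from 0.325 ± 0.0165 to 8.73 ± 0.591 FPKM. PSMB8-AS1, C5orf56 (IRF1-AS1) and BISPR also rose. PSMB8-AS1 was at most 0.110 FPKM in an untreated library and at 8.01 ± 0.957 with IFN-γ, C5orf56 at most 0.942 and at 12.4 ± 1.21, and BISPR at most 0.263 and at 1.65 ± 0.154, with 3, 3 and 1 of the 4 untreated libraries listed at 0. PSMB8-AS1 overlaps both PSMB8 and TAP1 on the other strand, which were at 39.8 ± 3.34 and 353 ± 18.5 FPKM with IFN-γ. C5orf56 overlaps IRF1 on the other strand. Without strand, the reads of these overlaps cannot be assigned to either gene. BISPR lies beside BST2 and does not overlap it. Camera did not call the list (adjusted p = 0.823), and its median (-0.09) and mean (0.57) log2 change differed in sign. Its direction was higher, and past the threshold, by fry (adjusted p = 3.8e-05) and in TPM (0.0044), with 3.8e-05 to 1.000 over all alternatives.

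Among stress and metabolic genes, camera called the cholesterol, heat shock and hypoxia lists higher, and none of these held with an estimated correlation. Of 19 genes of cholesterol synthesis and uptake, 11 rose and none fell (11 adjusted over the list alone), with HMGCS1, an early enzyme of the pathway, from 41.2 ± 2.03 to 62.1 ± 2.27 FPKM and MVK from 10.0 ± 0.793 to 14.6 ± 1.27. Camera gave adjusted p = 2.0e-05, and adjusted p = 0.127 with an estimated correlation and 0.383 in TPM. Of 13 heat shock genes, 4 rose, with the co-chaperone DNAJA1 from 204 ± 3.59 to 268 ± 12.5 FPKM and HSP90AA1 from 675 ± 11.6 to 834 ± 18.9 (adjusted p = 0.0109, and adjusted p = 0.402 with an estimated correlation, 0.0847 with quantile normalization and 0.658 in TPM). Of 19 hypoxia and glycolysis genes, 8 rose and 2 fell, with ADM from 5.75 ± 0.374 to 8.70 ± 1.13 and VEGFA from 32.7 ± 1.253 to 42.0 ± 1.10 (adjusted p = 0.0109, and adjusted p = 0.316 with an estimated correlation and 0.627 in TPM). Adjusted over the list alone, 5 heat shock genes and 9 hypoxia genes rose and 0 and 2 fell. The stress response, immediate early and cell cycle lists were not called (adjusted p = 0.216, 0.161 and 0.0950). The immediate early list was called lower without untreated replicate 4 (adjusted p = 0.0448, over all alternatives up to 0.558). The cell cycle list was called lower without IFN-γ replicate 4 (0.00616), with quantile normalization (7.6e-04) and in TPM without the short RNA genes (0.00703), over all alternatives up to 0.740. In the unfolded protein and integrated stress list 7 of 19 rose and 2 fell (8 and 5 adjusted over the list alone), with ATF3 from 1.82 ± 0.172 to 3.72 ± 0.266 and the chaperone HSPA5 from 99.3 ± 3.19 to 151 ± 6.84. Of 10 immediate early genes 2 rose and 3 fell (2 and 4 adjusted over the list alone), with EGR1 falling from 6.76 ± 0.789 to 4.30 ± 0.634. Of 33 cell cycle genes 3 rose and 4 fell, the same adjusted over the list alone, with CDKN2A rising from 7.58 ± 0.972 to 12.3 ± 2.05 and CCNE2 falling from 8.84 ± 0.363 to 6.64 ± 0.243.

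Reference genes moved little. Of 17 housekeeping genes, 5 rose and 1 fell, the same adjusted over the list alone (camera adjusted p = 0.115), with SDHA from 50.3 ± 0.651 to 62.4 ± 2.29 FPKM. ACTB (1424 ± 40.2 and 1537 ± 52.1) and GAPDH (1741 ± 14.7 and 1839.9 ± 150.4) did not pass. The median deviation of the housekeeping list in IFN-γ replicate 4 was 0.23, and without that library ACTB passed (log2 change 0.09, adjusted p = 0.0443, over all alternatives 0.0127 to 0.875). None of 38 ribosomal protein genes passed, over all genes or adjusted over the list alone (adjusted p = 0.648), with RPS27 at 4097 ± 131 and 4218 ± 354 FPKM. RPS27 passed as higher with quantile normalization (log2 change 1.13, adjusted p = 0.0161) and in TPM (0.84, 0.0163). Without IFN-γ replicate 4, where their median deviation was 0.40 (log2), that list was called lower (adjusted p = 5.4e-04, over all alternatives up to 0.924). Replication-dependent histone genes were called lower by camera (adjusted p = 0.00826, and adjusted p = 0.625 with an estimated correlation, 0.446 in TPM and 0.0518 without IFN-γ replicate 1), although 1 of 22 passed by itself, HIST1H4C from 1044 ± 25.2 to 772 ± 150.2, and none adjusted over the list alone. HIST1H4C lost its call without untreated replicate 4 or IFN-γ replicate 1, 2 or 3 (adjusted p = 0.0513 to 0.0548). The median deviation of the histone genes in IFN-γ replicate 4 was 0.46, and without that library the list was called lower at adjusted p = 3.8e-12, the lowest over the alternatives. The 13 mitochondrially encoded mRNAs were not analysed here.

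Markers of other cells were few. Of 17 leukocyte markers 2 passed the filter, too few for a list test, and neither was called, with CD68 at 0.607 ± 0.130 and 0.747 ± 0.115 FPKM. Of 3 glial markers 1 fell, TMEM119 from 24.8 ± 0.986 to 19.5 ± 1.16, with S100B at 0.914 ± 0.155 and 1.10 ± 0.336 (camera adjusted p = 0.648, direction lower, with a median log2 change of 0.21 and a mean of 0.06). Of 5 markers of fibroblasts, endothelium, epithelium and erythroid cells, 2 rose, PDGFRB from 8.20 ± 0.442 to 21 ± 1.52 and LUM from 20.3 ± 0.923 to 32.5 ± 6.29, and COL1A1 fell (adjusted p = 0.277). The counts of these last 2 lists were the same adjusted over the list alone.

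By the fixed rule the largest rises also included RARRES3, a retinoid-responsive gene listed at 0 in 4 of 4 untreated libraries and at 247, 274, 255 and 331 FPKM with IFN-γ, and GBP1P1, a pseudogene whose reads GBP1 can share, at most 0.0571 untreated and at 42.3 ± 1.41. The largest fall was SNORD3A, a small nucleolar RNA gene listed at 668784, 829316, 37842 and 741029 FPKM in the untreated libraries and at 0 in 4 of 4 with IFN-γ. DGKK, a diacylglycerol kinase, fell from 3.22 ± 0.151 to 0.635 ± 0.0851 FPKM, the natriuretic peptide gene NPPC from 2.29 ± 0.795 to 0.538 ± 0.274, LPPR4 from 7.71 ± 0.378 to 2.33 ± 0.161, KIAA0125 from 8.15 ± 0.619 to 2.67 ± 0.579, the homeobox gene DLX5 from 1.16 ± 0.136 to 0.366 ± 0.0590, the complement gene C7 from 21.7 ± 1.15 to 8.60 ± 0.679 and RERG from 1.20 ± 0.229 to 0.416 ± 0.0899. A listed 0 may be a failed estimate, which the values alone cannot show. H3F3A, a histone gene that every cell uses, was also listed at 0 in 3 of the 8 libraries. A failed estimate or a division of fragments between near-identical copies may give such zeros.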

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

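The depth test of IFN-γ replicate 4, the test of its trend with transcript length and both tests of the genes listed at 0 were chosen only after the result was seen. Each gene in the text and 5 totals per library were examined in each group for a library that stood apart, meaning that its gap to the nearest other library, divided by the range of the 4, exceeded Dixon's critical value for 4 samples. This held in 37 of 282 groups, where chance gives about 1 in 20 or 14.1. IFN-γ replicate 4 was the library in 16 of them.

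IFN-γ replicate 4 also stood apart as a whole. Over the tested genes, the variance of its deviation from the other IFN-γ libraries was 6.21 times the largest of the other three. Its deviation fell with transcript length (Spearman's rho = -0.206 across genes, which are not independent replicates, against at most 0.0234 in size in another library). Length here is the median over a gene's annotated transcripts. Other libraries had trends with GC content, the share of G and C bases in a gene's transcripts. Spearman's rho with it was 0.258 in untreated replicate 1 and 0.159 in IFN-γ replicate 3, against -0.0692 in IFN-γ replicate 4. Removing the trend with length left a ratio of 5.66, which argues against a trend with median length as the whole cause. The transcripts expressed in these cells can differ in length from that median, so length itself is not excluded. Its depth was 1.252 times that of untreated replicate 1, the highest of the 8, which excludes low depth. A length bias in library preparation may account for part of the deviation, the rest stays open, and no biological explanation was tested because the labels set no group apart within IFN-γ.

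IFN-γ replicate 4 stood apart in BST2 (84.2 FPKM, ratio 0.930), GAPDH (2064, ratio 0.882), HSPA5 (161, ratio 0.901), IFI27 (269, ratio 0.930), LUM (41.9, ratio 0.925), PSMA3 (301, ratio 0.862), PSMA6 (399.8, ratio 0.892), PSMB8 (44.8, ratio 0.868), TAP1 (381, ratio 0.880), VEGFA (43.6, ratio 0.892), the FPKM total (760353, ratio 0.928) and that total without SNORD3A (760353, ratio 0.928) as the highest of its group, and in APOL6 (69.4 FPKM, ratio 0.838), MAP1B (303, ratio 0.938), TRIM56 (6.19, ratio 0.882) and the number of genes at 0.5 FPKM or more (13417, ratio 0.852) as the lowest of its group.

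IFN-γ replicate 1 stood apart in NFKBIE (13.0 FPKM, ratio 0.920) as the highest of its group. IFN-γ replicate 2 stood apart in BISPR (1.88 FPKM, ratio 0.865) and HSP90AA1 (862, ratio 0.876) as the highest of its group. IFN-γ replicate 3 stood apart in C5orf56 (14.2 FPKM, ratio 0.855) as the highest of its group, and in APOL4 (65.2 FPKM, ratio 0.839) and IFIT3 (102, ratio 0.972) as the lowest of its group.

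Untreated replicate 1 stood apart in APOL3 (0.0296 FPKM, ratio 1), IDO1 (0.594, ratio 0.867) and SOCS1 (0.173, ratio 0.925) as the highest of its group, and in JAK2 (1.45 FPKM, ratio 0.835) as the lowest of its group. Untreated replicate 2 stood apart in APOL1 (0.0183 FPKM, ratio 1), BISPR (0.263, ratio 0.869), C5orf56 (0.942, ratio 1), DLX5 (1.36, ratio 0.970), HLA-DRA (0.0456, ratio 1) and IFITM1 (0.102, ratio 1) as the highest of its group. Untreated replicate 3 stood apart in GBP1 (0.0397 FPKM, ratio 0.869) and PSMB8-AS1 (0.110, ratio 1) as the highest of its group, and in QKI (4.06 FPKM, ratio 0.875) as the lowest of its group. Untreated replicate 4 stood apart in CD68 (0.801 FPKM, ratio 0.898) as the highest of its group, and in SNAI2 (4.29 FPKM, ratio 0.852) as the lowest of its group. A ratio of 1 marks a gene whose other 3 libraries were listed at 0.

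In 10 genes, 1 group was listed at 0 in 4 of 4 libraries while the other averaged at least 10 FPKM. They were CXCL9, CXCL11, GBP5, HLA-DRB1, PSMB9, RARRES3, BANCR, FAM155A and FAM155A-IT1 in untreated cells and SNORD3A with IFN-γ. FAM155A, a neuronal channel subunit gene on chromosome 13 (107163510 to 107866735), was at 24.5, 25.0, 25.7 and 24.4 FPKM with IFN-γ, its intronic transcript FAM155A-IT1 at 33.7, 37.3, 32.0 and 18.5 and the long non-coding RNA BANCR at 10.5, 10.9, 9.74 and 12.2. The lowest level of the other group would give at least 105 fragments in every library at 0, which excludes depth as the cause. Failed estimates written as 0 cannot be told apart from a change with IFN-γ, because no counts are at hand to decide. 1 other gene, H3F3A, was at 0 in libraries where its group would give 100 or more fragments. It is a histone gene, so a division of fragments between near-identical copies may also give its zeros, and it does not show that estimates failed.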

How the results depend on the processing

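Rescaling to TPM without the short RNA genes and removing the length trend were chosen only after the data were seen. Summing entries with the same symbol changes nothing, because no symbol is repeated. Of 123 called genes in the text, MIAT not counted among them, 99 kept their direction and their side of the threshold in every alternative that tested them. For 117 this held whichever library was left out, where the gene was tested. Some genes were not tested in every alternative, such as GRM4, tested in 17 of 21. Of 20 called lists, 11 kept both in every alternative. Leaving out 1 library gave 2336 (untreated replicate 2) to 3855 (IFN-γ replicate 4) changed genes and a MIAT change of -0.84 to -0.77.

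In TPM, 9555 genes changed, 9536 higher and 19 lower, 2305 by at least 2-fold (2290 higher, 15 lower), calls of list members reached 473 (from 295), 0 lists were lower and the MIAT change was -0.024. The log2 changes of CCNE2 (0.39), COL1A1 (0.33), EGR1 (0.15), GABRA4 (0.14), GAP43 (0.11), HIST1H4C (0.35), MYCN (0.66), NFKBIE (0.48), NR4A2 (0.060) and TMEM119 (0.46) turned positive, past the threshold only for MYCN, each below the median shift of 0.79 that SNORD3A brings, as that shift is -0.10 without the short RNA genes. ACTB, GAPDH, CD68, S100B, IFNGR1, IFNGR2 and RPS27, not called in the main fit, passed as higher in TPM, by 0.82 to 0.98, about the size of the shift. TPM without the short RNA genes gave 1201 genes higher and 103 at least 2-fold lower, and quantile normalization 2564 lower and 71 at least 2-fold lower; the cause was not tested. The count of 37 genes at least 2-fold lower became 12 with a pseudocount of 1, which shrinks changes of low genes, 61 without the filter and 23 with a filter at 1 FPKM, where more or fewer genes are tested.

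Of the lists, 11 were called higher and 0 lower with an estimated correlation, and fry called 26 higher and 1 lower. Among those higher by fry were 8 lists that camera did not call: NF-κB (adjusted p = 3.7e-05), catecholaminergic identity (0.0246), mesenchymal state (5.4e-04), schizophrenia candidates (0.0171), GOMAFU-associated proteins (0.00156), long non-coding RNAs (3.8e-05), unfolded protein and stress responses (0.0105) and markers of fibroblasts and other cells (5.4e-04). Leaving out 1 library gave 1 (IFN-γ replicate 1) to 4 (IFN-γ replicate 4) lists lower. The ribosomal list turned to lower without IFN-γ replicate 4 (adjusted p over left-out libraries 5.4e-04 to 0.773), and the long non-coding RNA list turned to higher by fry (adjusted p = 3.8e-05) and in TPM (0.0044); the cause was not tested.

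The labels do not say whether the replicate numbers pair the libraries. Deviations of same-numbered libraries correlated only weakly, at -0.03, 0.08, 0.06 and 0.06, although 3 of the 4 IFN-γ libraries correlated best with their own number. These correlations were not tested, so pairing stays open. With the number as a replicate block, 2656 genes changed, 1639 higher and 1017 lower.

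Depth limits the low end: 1 fragment per kilobase is worth 0.0482 to 0.0703 FPKM, and no counts are at hand to weight genes by their counting error.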

Other observations

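The family tests of the proteasome core, APOBEC3, butyrophilin, metallothionein, ephrin, and GABA and glutamate receptor genes, the count of lists in the less frequent direction over splits, the neighbour counts without listed genes, the comparison of MIAT with other long non-coding RNAs and the genes named from all families, were chosen only after the results were seen. 12 families defined by gene symbol were tested by camera with adjustment over the families, and 10 were called, 6 higher and 4 lower, of which 3 passed with an estimated correlation. Several lost their call in other scalings, as given below. Camera's direction was the same in 4 other scalings and without IFN-γ replicate 4. The median log2 change relative to all genes turned positive for clustered protocadherins without that library (0.0335), and for semaphorins without it (0.0260) and with quantile normalization (0.00451).

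Of 14 constitutive subunits of the 20S proteasome core, 10 rose, such as PSMA3 from 95.7 ± 6.29 to 243 ± 39.0 FPKM and PSMA6 from 131 ± 4.98 to 332 ± 45.7 (camera adjusted p = 4.7e-07, and adjusted p = 0.259 with an estimated correlation), and of 19 subunits of the 19S regulator 9 rose by smaller steps (camera adjusted p = 0.00297, and adjusted p = 0.435 with an estimated correlation, 0.246 with quantile normalization, where 1 passed above and 1 below the median of all genes, and 0.559 in TPM). All 5 tested APOBEC3 cytidine deaminases, which restrict retroviruses, rose, with APOBEC3G from 0.816 ± 0.0508 to 9.31 ± 0.717 and APOBEC3C from 4.83 ± 0.494 to 14.9 ± 0.795 (adjusted p = 5.6e-07, and adjusted p = 0.0103 with an estimated correlation). Of 6 butyrophilins 5 rose and 1 fell (adjusted p = 5.6e-07, and adjusted p = 0.0103 with an estimated correlation), among them BTN3A1 from 4.61 ± 0.130 to 31.2 ± 0.902, BTN3A2 from 3.07 ± 0.184 to 32.0 ± 0.805 and BTN3A3 from 2.61 ± 0.178 to 33.2 ± 0.820, a subfamily that takes part in recognition by γδ T cells. Of 3 metallothioneins 2 rose, MT2A from 10.6 ± 1.12 to 92.9 ± 8.24 and MT1X from 15.8 ± 3.85 to 41.0 ± 6.38 (adjusted p = 0.00634, and adjusted p = 0.0863 with an estimated correlation).

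In several families of neuronal surface genes more members fell than rose in the main fit. In TPM, where all genes shift up, members called above the median of all genes outnumbered those called below it. The counts were 3 and 0 for ephrins and their receptors, 3 and 1 for potassium channels, 3 and 2 for GABA and glutamate receptors and 14 and 9 for clustered protocadherins. That shift alone can bring this about. Rescaling to TPM multiplies all genes of a library by the same factor, so medians relative to all genes stay nearly the same by construction. In TPM they were -0.292 (log2) for ephrins and their receptors, -0.298 for potassium channels, -0.135 for GABA and glutamate receptors and -0.0990 for clustered protocadherins. These medians therefore add nothing to the main fit. Of 15 ephrins and their receptors, which guide axons, 9 fell and 3 rose (adjusted p = 0.00854, adjusted p = 0.162 with an estimated correlation, 0.0607 with quantile normalization and 0.0784 in TPM), with EFNB2 falling from 2.69 ± 0.177 to 1.24 ± 0.187 FPKM and EPHA5 rising from 2.59 ± 0.192 to 4.46 ± 0.506. Of 16 voltage-gated potassium channel genes 5 fell and none rose (adjusted p = 0.00233, adjusted p = 0.0452 with an estimated correlation, 0.0784 in TPM), with KCNH4 falling from 3.43 ± 0.458 to 1.89 ± 0.185. Of 15 GABA and glutamate receptor genes 5 fell and 2 rose (adjusted p = 0.0196, adjusted p = 0.162 with an estimated correlation, 0.0607 with quantile normalization, 0.421 in TPM and 0.0716 without IFN-γ replicate 4). GABRB1 fell from 7.53 ± 1.08 to 3.26 ± 0.267 and GABRA4 from 31.1 ± 0.972 to 19.6 ± 0.308, while GRM4 rose from 0.0436 ± 0.0117 to 1.06 ± 0.142. Clustered protocadherins (6 of 50 fell, 3 rose) gave adjusted p = 0.0467 (adjusted p = 0.626 with an estimated correlation), and 0.0501 to 0.874 in the other scalings and without IFN-γ replicate 4. Without that library 5 passed above and 5 below the median of all genes. Complex I genes (3 of 37 rose) gave adjusted p = 0.0196 (adjusted p = 0.626 with an estimated correlation), 0.543 with quantile normalization, 0.492 in TPM and 0.558 without that library. Semaphorins (adjusted p = 0.414, 4 of 12 lower and 2 higher) and the vacuolar ATPase (adjusted p = 0.0603, 2 of 19 higher) were not called.

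Genes beside strongly induced genes rose more often than others. Within 50 kb of 100 genes that rose by at least 4 log2 units, 24 of 102 neighbours that overlap none of them were called higher (23.5%). Among 12480 other genes the share was 12.9% (Fisher's exact test, p = 0.00295). This argues against reads shared with an overlapping gene as the whole cause, although neighbours in a cluster are not independent. Of 17 genes that overlap a strongly induced gene, 8 were called higher (47.1%), so shared reads may add to the pattern. Of the neighbours without overlap, those downstream on the same strand rose in 9 of 33 and the others in 15 of 69 (Fisher's exact test, p = 0.620). These are too few to say whether read-through contributes. Clusters of related interferon genes may account for part of it: without the genes of the fixed lists 17 of 93 rose against 12.2% of others (Fisher's exact test, p = 0.0804), which leaves this open.

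Among 599 tested long non-coding RNA genes, 51 rose and 32 fell. 20 of the 599 had a log2 change below that of MIAT. Of 99 with a mean at least as high, a cut set by MIAT itself, 13 rose and 13 fell, and MIAT had the largest fall of these.

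The libraries can be split into 4 and 4 in 35 ways, the real split included. Only the real split gave 3039 changed genes and 423 changed at least 2-fold, with 1 as the highest of the other splits in both. The other splits mix treated and untreated libraries, which widens the spread within each side, so few calls were built in. These counts therefore do not decide on chance, nor do they tell IFN-γ from another difference between the groups. Chance cannot be excluded for the number of lists called higher, where 8 splits gave at least the real 18 and the highest other was 19. The same holds for the number called in the less frequent direction (7 splits, real 2, which are the lists called lower, highest other 4) and for families (6 splits, real 10, highest other 11). The splits with the highest numbers of lists exchange a single library of each group, so they keep most of the real contrast.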
